A study of Mus musculus with 12 samples.

How the data were processed

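The series measured 5-formylcytosine (5fC), an oxidised form of 5-methylcytosine, in mouse embryonic stem cells by a bisulfite-free method. Per the labels' protocols, azido-indandione was coupled to 5fC, the labelled base was read as T instead of C after amplification, and the azide carried a biotin handle for pull-down on streptavidin. The labels describe 12 libraries in 6 groups of 2 replicates. The groups are Tdg knockout and Tdg floxed control cells, each as unlabelled input, labelled input and pull-down output.

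The authors deposited 1 site list per genotype, and these lists are the only measurements used here. Each deposited row gives a chromosome, a start and an end, and the start equalled the end in all 139027 knockout rows and all 32685 control rows. The values are positions of single bases, with no level, read number, score, strand or replicate beside them. The genotype of each list was taken from its name, which matches a cell line named in the series' design text. No position in the lists depends on that name, but every direction between genotypes does. The submitters' processing notes name Bismark 0.8.3, HOMER and the mouse build mm9, without a role for each. The rule by which a site was listed, the input libraries' part in it and whether replicates were pooled are not given in the sources used here. Whether positions count from 0 or from 1 is also not given, so coordinates are printed as listed. Chromosome names of unplaced sequence and site positions beyond the GRCm38 gene ends on chromosome 1 are those of mm9.

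The gene table used here is on GRCm38, another build, and coordinates were not carried from one build to the other. Sites were therefore not tied to genes, exons, introns or promoters, and the comparison of genomic features and the tests of 12 fixed gene lists were not run. Levels of 5fC, pull-down output against input, and agreement of replicates were planned and not run, since the lists hold positions only. Strand symmetry was planned for sites with a strand. Without one, the planned fallback was used: the share of sites with another listed site exactly 1 base away. In a CpG dinucleotide the cytosines of both strands are 1 base apart.

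The lists were read in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The totals of the lists and their ratio include unplaced sequence, and all other comparisons used 19 autosomes and X. Ratios of list lengths have exact conditional 95% intervals and shares have exact Clopper-Pearson 95% intervals. Differences and ratios of shares have normal and log-normal intervals. The depth of each library is unknown, and all of these intervals cover counting error only. Sites in clusters are not independent, so the intervals are too narrow for any statement beyond these lists. With 1 list per genotype, a difference between genotypes has no replicate check and no p-value.

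Overlap of the lists was counted at the exact base and within 1 base, 100 bases and 1 kb. It was compared with 1000 circular shifts of the control list along each chromosome, which keep the spacing within each list. The p-value is one-sided, the smallest it can take is 0.001, and Benjamini-Hochberg adjustment was over the 4 distances. Clustering was compared with 100 uniform placements of the same number of sites over the span from the first to the last site of each chromosome. To compare lists of unequal length, the knockout list was thinned at random to the control number 100 times. Densities are sites per Mb of the same span. Ratios of pair counts by distance have 95% intervals from 1000 bootstrap draws over the 20 chromosomes, as has the difference of these ratios between genotypes. In a further test, the repeat length that gave the highest first ratio on odd autosomes was applied to even ones, and the reverse. Both tests were chosen after the values were seen. The overlap and adjacent-base scripts were tested on simulated lists. They found 100% of 13060 planted shared sites and 100% of 27772 planted sites in adjacent pairs. The shift test called 3 of 100 pairs of independent clustered lists at 0.05. Those lists were shorter than the real ones, were tested within 1 kb only and had no shared preference for the same regions. Calls that such a preference would cause are therefore not covered.

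Choices of test, comparison and alternatives were made before the data were examined, except where stated. Named regions follow a rule of that kind for sites that are not tied to genes. The rule takes the 10 windows of 10 kb with the most sites per genotype, ties by position, and the 3 longest runs of consecutive sites no more than 100 bases apart. Length of a run was counted in sites, not in bases. Its parts on levels and p-values do not apply to these lists. Windows with many sites in 1 list and none in the other, the last stretch of X, the start of the 34.1 kb used for its density and the distances in the pair counts were chosen after the values were seen. Not in the earlier plan were the counts at nearby offsets, the comparison of same and adjacent bases between lists, and adjacent-base shares by sharing. Also outside it were the correlation over 1 Mb windows, the distances of unshared sites and the joining of sites into regions. Alternatives were merging adjacent sites, autosomes only, wider overlap distances, thinning, and other distances for clustering.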

Results

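5fC is the second oxidation product made from 5-methylcytosine by TET enzymes, and TDG is the DNA glycosylase that removes it ahead of base excision repair. The series mapped 5fC at single-base resolution in Tdg knockout mouse embryonic stem cells and in floxed control cells that keep TDG. The labels give 2 replicates for each of 3 library types per genotype, and the values used here are 1 list of 5fC positions per genotype on mm9. Neither list gives a read depth or a 5fC level for a site. The lists hold no value of Tdg itself, so the genotype labels were not checked from the data.

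The first comparison asked how many 5fC sites were listed with and without TDG. The knockout list held 139027 sites and the control list 32685, a ratio of 4.25 (95% interval 4.20 to 4.31). On autosomes the numbers were 138649 and 32614, again a ratio of 4.25. The excess was spread over the genome: the ratio averaged 4.26 ± 0.158 (SD over 19 autosomes), from 3.97 on chromosome 8 to 4.59 on chromosome 6. With each pair of adjacent sites counted as 1, the ratio was 3.94. There was no replicate check of this difference, and the number of listed sites depends on read depth and on the authors' threshold, which are both unknown.

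Site density varied among chromosomes in the same way in both genotypes. Chromosome 11 was the densest, with 92.6 knockout and 22.9 control sites per Mb, and chromosome 14 the sparsest autosome, with 39.1 and 9.40. The mean over autosomes was 58.4 ± 13.8 sites per Mb in knockout and 13.8 ± 3.40 in control cells (SD, n = 19 autosomes). Over 2423 autosomal windows of 1 Mb, site numbers of the 2 lists had a Pearson correlation of 0.966 and a Spearman correlation of 0.960. This is a correlation across windows, which are not independent replicates.

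The X chromosome held few sites in both genotypes, 306 in knockout and 56 in control cells. Its density was 1.92 knockout sites per Mb and 0.351 control sites per Mb, which is 0.0334 (0.0297 to 0.0373) and 0.0260 (0.0196 to 0.0337) of the autosomal density. X made up 0.220% of knockout sites and 0.171% of control sites, a ratio of 1.28 whose 95% interval of 0.966 to 1.71 includes 1. The X sites were unevenly placed, since 76 of the 306 knockout sites lay in the last 17.9 kb with sites, from 166416138 to 166434073. That stretch held 1 control site, against 17.9 expected at the ratio of the list lengths. It was singled out after its values were seen, and whether the lists used here are complete on X was not checked. Without the last 34.1 kb up to the last site, X density relative to autosomes was 0.0251 (0.0219 to 0.0285) in knockout and 0.0255 (0.0192 to 0.0332) in control cells.

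**Figure D1:**
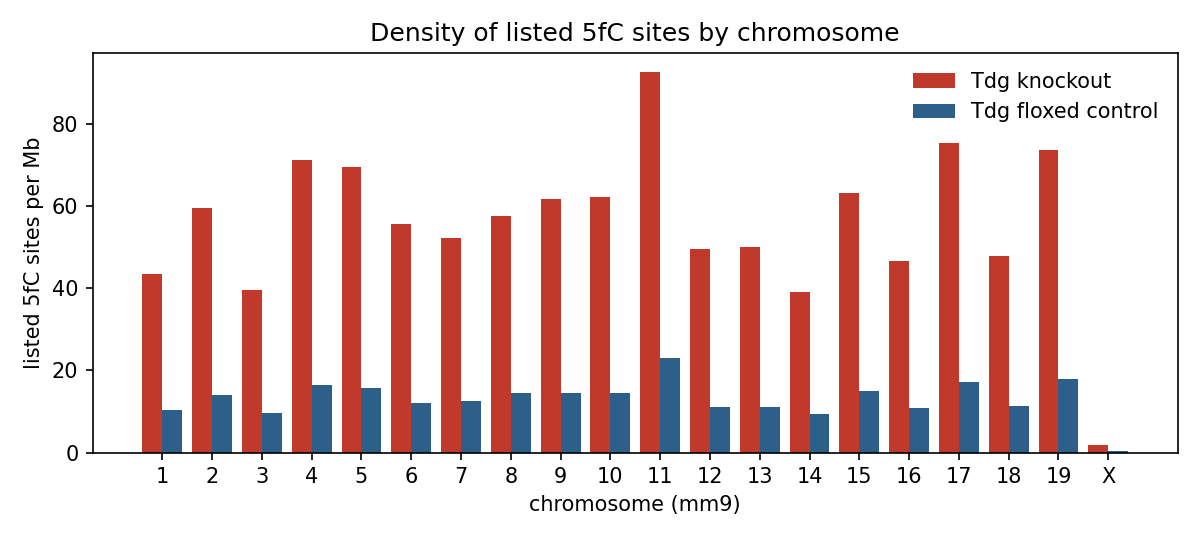
Listed 5fC sites per Mb on each mm9 chromosome, with knockout bars in red and control bars in blue. Chromosome 11 is highest in both lists (92.6 and 22.9 per Mb) and X is lowest (1.92 and 0.351 per Mb).

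The next comparison asked whether bases carrying 5fC in control cells also carried it without TDG. Of the control sites on placed chromosomes, 13810 (42.3%, 41.7 to 42.8) were listed at the exact same base in knockout cells, and these were 9.94% (9.78 to 10.1) of the knockout list. The share was 42.1% ± 1.87 (SD) over the 19 autosomes, from 39.0% on chromosome 19 to 45.2% on chromosome 12. Shifted control lists shared 2.05 sites on average and 7 at most (one-sided permutation p = 0.001, the smallest that 1000 shifts can give; adjusted p = 0.001). The shifts also remove any shared preference for the same regions, so nearby offsets were counted too. Offsets of 5 to 50 bases held 131 pairs each on average, but most of those bases need not be cytosines that can carry 5fC, which limits them as a background. The bases 1 above and 1 below held 3112 and 3137 pairs, against 13810 at the exact base.

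Control sites that were not shared still lay close to knockout sites. The 18860 control sites listed only in that genotype had a median distance of 115 bases to the nearest knockout site. Of them, 47.7% lay within 100 bases of one and 83.4% within 1 kb, and no shift test was run on them. Within 100 bases of a knockout site were 69.8% of all control sites, and within 1 kb 90.4%, against 0.871% and 5.67% after shifts (one-sided permutation p = 0.001 and adjusted p = 0.001 for each). These shares include the exact matches, which alone exceed the highest shift counts of 374 and 2784. The p-values therefore say nothing about the unshared sites. In the other direction, the 125145 sites listed only in knockout cells had a median distance of 3601 bases to a control site, and 37.0% lay within 1 kb. The control list is the shorter one, which lengthens these distances by itself, and equal list lengths were not compared here. Only 1043 control sites (3.19%) were more than 10 kb from any knockout site.

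**Figure D2:**
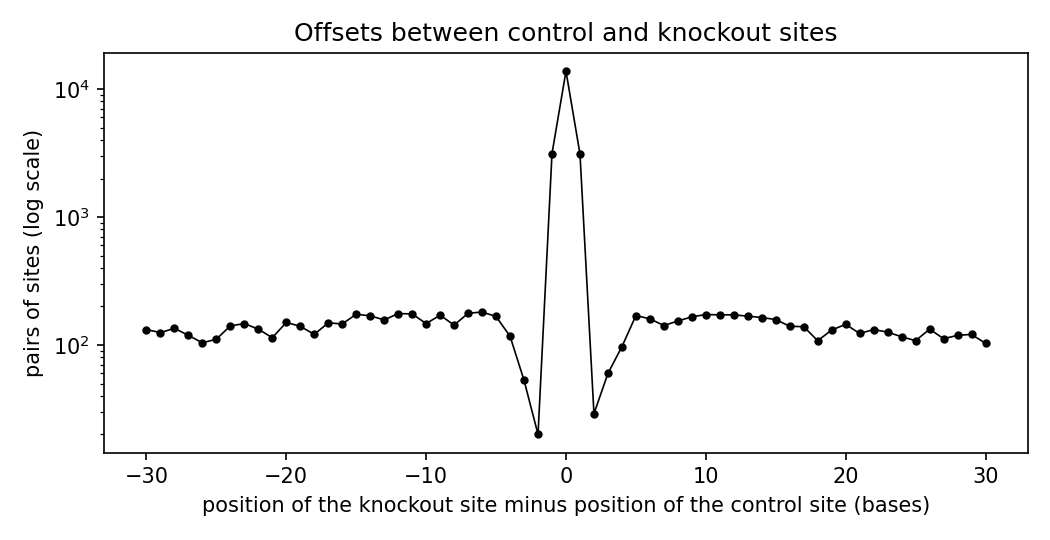
Number of control-knockout site pairs (log scale) at each offset from 30 bases below to 30 bases above the control site. The exact base holds 13810 pairs, the bases 1 above and 1 below hold 3112 and 3137, and the base 2 above holds 29.

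Sites on neighbouring bases, as the cytosines of both strands of a CpG would be, were compared next. In knockout cells 27070 sites (19.5%, 19.3 to 19.7) had another listed site 1 base away, and in control cells 1726 (5.28%, 5.04 to 5.53). Among pairs of knockout sites, a distance of 1 base occurred 13536 times and a distance of 2 bases 130 times. The share in knockout cells was larger by 14.2 percentage points. Knockout lists thinned at random to the control number had a median of 4.60% (4.14 to 5.09 over 100 draws), below the control value. Random thinning removes neighbours by construction, so the thinned value follows from the knockout share and the list lengths. It shows that the shares depend on list length and does not test whether the genotypes differ. Given a control site, a knockout site lay on the same base in 13810 of 32670 cases and on an adjacent base in 6249 (95% interval of this share 18.7% to 19.6%). The same base was the more frequent on all 20 chromosomes, and the ratio of the shares was 2.21. Knockout sites shared with control had an adjacent knockout site in 25.4% of cases (24.6 to 26.1), and unshared knockout sites in 18.8%, with 95% intervals that did not overlap.

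5fC sites were clustered in both genotypes. The median distance to the nearest other site was 87 bases in knockout and 2263 bases in control cells, and 83.4% and 42.8% of sites had another within 1 kb. Uniform placement gave 11.3% and 2.81% on average, with highest values of 11.7% and 3.07% over 100 draws. Those placements could fall on any base, including bases that cannot carry 5fC, so the gap from them need not be particular to 5fC. Thinned knockout lists had 38.1% (37.4 to 38.9) of sites within 1 kb of another, below the control share. Thinning removes neighbours here too, so these draws do not test whether the genotypes differ in clustering. Of windows of 10 kb, 9081 held 5 or more sites in knockout and 325 in control cells, against a median of 259.5 in thinned knockout lists.

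**Figure D3:**
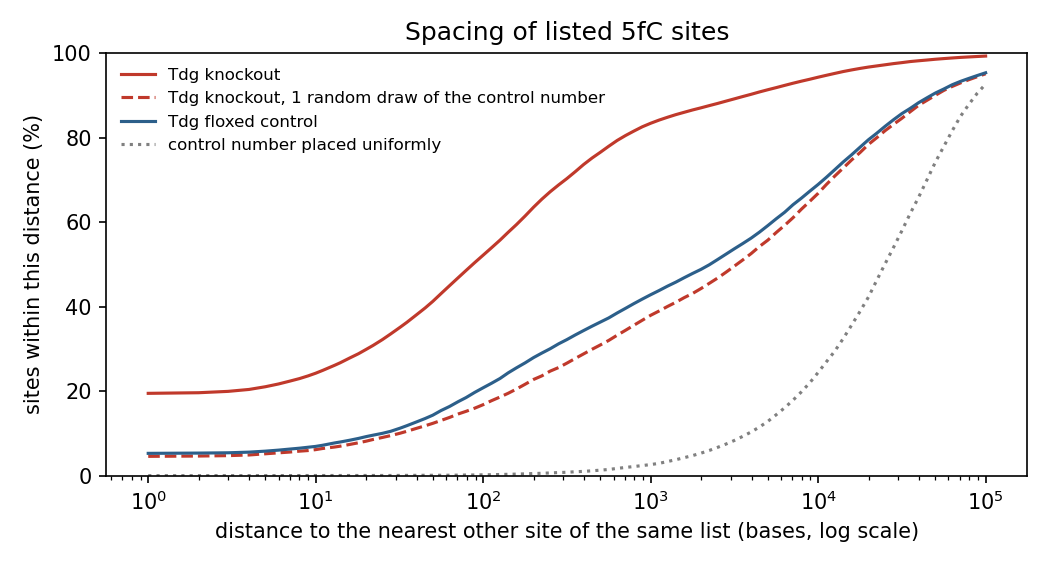
Percentage of sites with another site of the same list within the distance on the x axis (bases, log scale), for knockout, control, 1 thinned knockout draw and uniformly placed control sites. At 1 kb the knockout curve is at 83.4% and the control curve at 42.8%.

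Joining sites no more than 1 kb apart gave 60036 knockout regions and 24737 control regions. Regions of 3 or more sites numbered 19947 in knockout and 1415 in control cells. Of the control regions of 3 or more sites, 97.9% lay within 1 kb of a knockout site, and of the knockout ones 52.1% lay within 1 kb of a control site. The knockout list is the longer one, which raises the first of these shares by itself, and equal list lengths were not compared. All 325 control windows with 5 or more sites held knockout sites, and 300 of them held 5 or more.

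The densest window was the same in both lists, on chromosome 12 from 20230000 to 20239999, with 35 knockout sites, 15 control sites and 11 shared bases. The window on chromosome 11 from 99000000 to 99009999 held 28 knockout and 9 control sites, and that on chromosome 4 from 141610000 to 141619999 held 27 and 8. These 3 windows were among the 10 densest of both genotypes. Other dense knockout windows were on chromosome 5 from 122960000 to 122969999, with 29 knockout and 5 control sites, and on chromosome 4 from 140870000 to 140879999, with 26 and 3. On chromosome 10, the window from 61790000 to 61799999 held 25 knockout and 6 control sites. On chromosome 15, that from 82080000 to 82089999 held 25 and 5, and on chromosome 5, that from 129090000 to 129099999 held 23 and 6. The remaining pair of the knockout top 10 lay at the end of X: the window from 166410000 held 30 knockout and 0 control sites, and that from 166420000 held 34 and 1. In control cells, the windows on chromosome 2 from 33640000 to 33649999, chromosome 4 from 108570000 to 108579999 and chromosome 16 from 90160000 to 90169999 held 9 control sites each, with 17, 16 and 12 knockout sites. Each of the 4 remaining control windows held 8 control sites. They started at 137670000 on chromosome 1, 33450000 on chromosome 2, 41040000 on chromosome 4 and 77490000 on chromosome 7, and held 8, 11, 10 and 7 knockout sites. What is annotated at these positions was not analysed here.

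Some dense stretches were listed in knockout cells alone. The 3 runs with the most knockout sites, each no more than 100 bases from the next, had 0 control sites each. They had 14 sites on X from 166419767 to 166419909, 11 on chromosome 4 from 131457041 to 131457352, and 10 on chromosome 2 from 168136651 to 168136919. The control run with the most sites, on chromosome 4 from 86283535 to 86283745, had 7, with 5 knockout sites in the same stretch and 3 shared bases. The other control runs, on chromosome 7 from 137362548 to 137362711 and on chromosome 8 from 19863005 to 19863218, had 5 sites each, with 2 and 3 knockout sites. Of 1289 windows with 10 or more knockout sites, 135 (10.5%) had no control site. Part of this follows from the shorter control list, since knockout lists thinned to its length left a median of 57 of these windows empty (43 to 73). Those lists are draws from the knockout list itself, so the difference from 135 does not test the genotypes. Examples chosen after the values were seen were chromosome 17 from 83890000 to 83899999, with 23 knockout and 0 control sites, and chromosome 18 from 75510000 to 75519999, with 20 and 0. In the other direction, 1470 of 21103 windows with a control site (6.97%) had no knockout site, and none of these held more than 4 control sites.

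Distances between pairs of knockout sites were also counted, in ranges chosen after their profile was seen. Pairs 170 to 200 bases apart were 1.16-fold as frequent as the geometric mean of the ranges midway to the neighbouring repeats, with a lower 95% bound of 1.11 and a ratio above 1 on 19 of 19 autosomes. At 355 to 385 bases the ratio was 1.11 (1.07 to 1.15), above 1 on 17 autosomes, and at 540 to 570 bases 1.08 (1.02 to 1.15), above 1 on 13. Pairs of control sites had a ratio of 1.01 (0.890 to 1.15) at 170 to 200 bases, above 1 on 8 of 19 autosomes. Pairs of a control and a knockout site had 1.07 (1.004 to 1.14) there, above 1 on 11 of 19. Their ratios at the farther ranges were 1.06 (0.986 to 1.13) and 1.04 (0.982 to 1.09), with intervals that include 1. The knockout ratio minus the control ratio was 0.152 (0.0260 to 0.272, bootstrap over chromosomes) at 170 to 200 bases. That range had been picked from the knockout profile, which favours a higher knockout ratio. The bootstrap resampled chromosomes of 1 list per genotype, so its interval does not cover variation between libraries, and the difference has no replicate check. At the farther ranges the intervals of the difference included 0, from -0.155 to 0.219 and from -0.141 to 0.236.

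**Figure D4:**
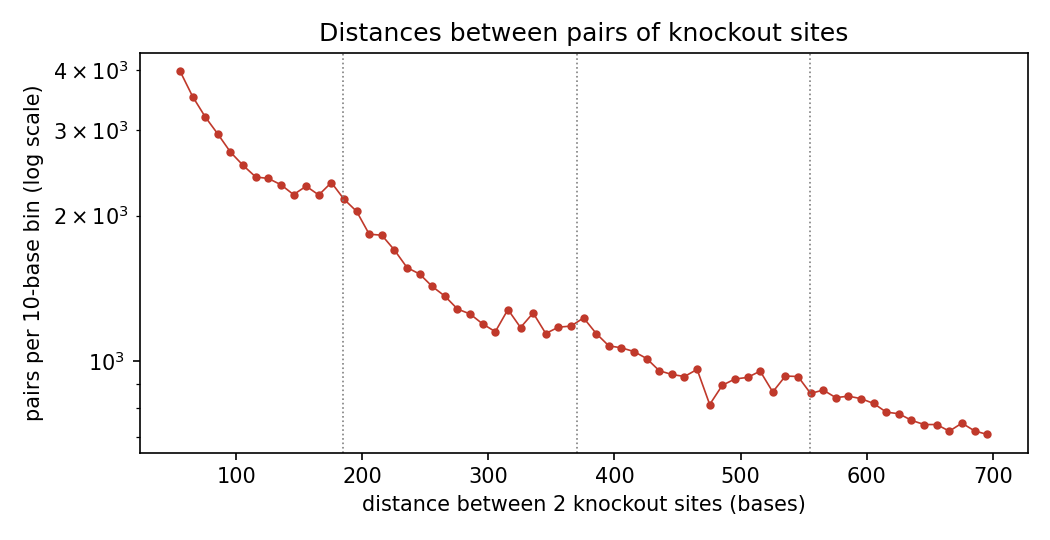
Pairs of knockout sites per 10-base bin of distance (log scale), with dotted lines at the centres of the 3 lag ranges compared. Counts fall with distance and level off around the first line: the bins from 161 to 170, 171 to 180 and 181 to 190 bases hold 2206, 2340 and 2162 pairs.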

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

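Sequence that mm9 does not place on a chromosome position entered the totals of the lists and no other comparison of the report. It held 72 listed sites in knockout and 15 in control cells, noted as signal outside the chromosomes compared. Of these, 11 were at the same base in both lists. Input libraries were not used here, and no biological explanation was tested.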

How the results depend on the processing

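Of 13 alternatives run over 5 results, 3 left a value within its interval: the ratio of list lengths on autosomes, adjacent bases on autosomes, and the X share without its last stretch. The last of these was not stable in direction: the ratio of X shares went from 1.28 to 0.983, across 1. It stayed inside the main interval because that was wide, from 0.966 to 1.71. Sharing stayed above its shifts at the 3 wider distances (50.7% to 90.4% of control sites) and in the 1 thinned list tested (p = 0.001, the smallest that permutation can give). The wider distances contain the exact matches, which alone exceed every shift count there, so they are no separate check. The thinned share, 9.94%, is set by construction. The adjacent-base autosome and X stretch alternatives were chosen after seeing the data. Counting adjacent sites as 1 gave a ratio of list lengths of 3.94 and a clustering difference of 39.8 percentage points. That difference, 40.6 points within 1 kb, was 31.4 within 100 bases and 25.4 within 10 kb. Thinning the knockout list to the control number, in 100 draws separate from those of the report, reversed both the clustering difference, to -4.77 points, and the adjacent-base difference, to -0.72 points. Thinning removes neighbours by construction, and the cause of the remaining differences was not tested. No paired analysis was possible because the lists carry no replicate columns. Not run, for want of levels, depth or annotation on mm9, were a stricter threshold, other coverage minima, shared sites or autosomes only for levels, leaving out replicates, the unlabelled input, and other promoter and gene definitions. Read depth is unknown, so it limits every count by an amount that was not measured.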

Other observations

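All tests in this part were chosen after the results were seen, on the lists that showed them, so each explanation is a hypothesis.

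Sites were scarce on X in both genotypes, at 0.0251 of the autosomal density in knockout cells without the last stretch, far below the 0.5 that a single copy with sites listed in proportion would give. Fewer modified CpGs, each called as often as elsewhere, would keep the autosomal adjacent-base share, but 0 of 105 isolated knockout X sites, with no further site than an adjacent one within 10 kb, had an adjacent site (upper 95% bound 3.45%), against 18.7% (17.9 to 19.4) on autosomes, and 10 of all 230 did (4.35%, 2.10 to 7.85). The argument holds for the knockout list alone, since 2 of 32 isolated control X sites had one (6.25%, 0.766 to 20.8) against 4.72% on autosomes, and 6 of 55 control X sites had a knockout site on the adjacent base (10.9%, 4.11 to 22.2), an interval that includes the share over all chromosomes. Of the same 55, 20 had a knockout site on the same base (36.4%, 23.8 to 50.4), an interval that includes the 42.3% over all chromosomes. Bases of X listed in control cells may be those with more reads, so this share does not settle the depth on X. A depth minimum that single-copy sequence rarely reaches remains open: the last 34.1 kb of X up to the last site, a span chosen after seeing the sites, had 38.8 times the autosomal density in knockout cells, as more copies might give, but 1 control site there leaves a range of 0.0549 to 12.1 times. Lower depth and lower 5fC on X cannot be told apart without read numbers, and neither fixed variants among the X sites nor the completeness of the lists on X was checked.

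A control site was matched by a knockout site on the same base more often than on the adjacent base. Strain variants read as C-to-T changes would sit on 1 strand and lower the adjacent-base share of shared sites. That share was 25.4%, above the 18.8% of unshared sites. Shared sites also lay nearer to other knockout sites, at a median of 56 bases against 92 for unshared sites. Unshared sites are thus not a like baseline, and variants at part of the shared sites stay open. Unequal 5fC on the strands of a CpG may underlie the excess at the same base, as may a strand or sequence preference of labelling, pull-down or mapping. These were not tested, since the lists carry no strand.

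Pairs of knockout sites showed small excesses at repeated distances. Without the densest 1% of windows, the ratio at 170 to 200 bases was 1.16, so it did not depend on those windows. Windows were left out by site number and not by sequence, so tandem repeats in other windows stay open. A single typical width of regions or fragments would give no excess at the second distance if pair numbers fell by a constant factor per base. With the length taken from the first distance on odd autosomes, the ratio at the second was 1.06 (lower 95% bound 1.03) on the 9 even ones. In the reverse split it was 1.15 on the 10 odd ones, with an interval above 1. A fall that steepens with distance could raise the ratio without any repeat, so these values do not decide on a single width. Spacing of modified CpGs by nucleosomes stays open, since at the farthest distance these splits gave 1.11 (1.01 to 1.24) and 1.05 (0.986 to 1.11). Repeat lengths of 180, 190 and 200 bases kept all 3 ratios above 1, 170 bases put the ratio at the second distance at 0.995, and 160 and 210 bases put both farther ratios below 1, so the pattern rests on a length picked from these data.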
